A study of Mus musculus with 6 samples.

How the data were processed

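Total RNA of LT-HSCs sorted as eGFPlo or eGFPhi from the bone marrow of Trim47+/eGFP mice was profiled in 6 libraries, 3 per group. Per the labels, RNA with an integrity number above 7.0 was selected on poly-T beads, made into paired-end libraries with a stranded mRNA kit and sequenced on an Illumina NovaSeq instrument. The gate that defined LT-HSCs, the number of animals and whether replicates are separate animals are not given in the sources used here. The labels name CASAVA 1.8, HISAT2, StringTie and edgeR without their roles, and list the genome builds hg38 and GRCm38. The read counter, its strand setting and its handling of reads shared between genes are not given in the sources used here.

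The deposited table gives counts per gene and library, per the file headers, and these were treated as raw read counts. It also gives FPKM values (counts scaled by gene length and library total) that the authors computed from the same counts. It holds 26776 genes, none of them 0 in all libraries, of which 26710 have an identifier in GENCODE M21 and 26508 the same coordinates as there, so positions are on GRCm38. The gene length implied by the FPKM values equalled the sum of a gene's distinct annotated exons, within 0.5%, for 98.9% of genes; for the 14548 genes with several isoforms this length was a median of 1.41 times the length of the merged exons. FPKM therefore depends on the number of annotated isoforms, and levels are given as CPM. Among them 2186 genes overlap exons of another gene on the same strand and 4651 on the other strand; of the 117 genes selected by the naming rule 10 and 22 do. The abundant small RNAs Rn7s1, Rn7s2, Rn7sk, Rpph1 and Gm24447 were summed. They made up 2.50 to 2.52% of counts in the eGFPlo libraries and 3.07 to 3.15% in the eGFPhi libraries. Mitochondrial ribosomal RNAs made up 11.2 to 11.6% and 12.2 to 12.3%.

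Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its default settings (a minimum count of 10 and a minimum total of 15), which left 18081 genes and 99.7 to 99.9% of each library's counts. TMM factors, quasi-likelihood F tests with group as the only term, and Benjamini-Hochberg adjustment over the tested genes followed, with a threshold of 0.05. CPM used these factors and the kept counts. A gene with no count in a group was given a bound on its fold against 3 counts over that group, which is 0.0680 CPM in eGFPlo and 0.0529 CPM in eGFPhi; a gene with 1 to 3 counts was given a ratio with a 95% counting interval. Such bounds and intervals cover counting error only. Totals of 11221070 to 26058391 counts put the floor of a single library, 3 counts, at 0.115 to 0.267 CPM.

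The 31 gene lists were tested with camera on log2 CPM with a preset inter-gene correlation of 0.01 and adjusted over the lists. The comparison, the lists, the test, the alternatives (except those named below) and the rule for naming genes were fixed before the data were examined. By that rule the text names Trim47. It also names, among genes past the threshold whose groups do not overlap, with a mean of at least 1 CPM and no predicted-model symbol, the 10 with the largest rise and the 10 with the largest fall. From each list it names the members past the threshold with the smallest p, at most 4; the selection took 4 where the list's test passed and 2 elsewhere, a narrowing made after the data were seen. A few genes so selected are not described in the text. A gene outside this rule was chosen after its values were seen, and the text says so.

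Replicate numbers are shared between groups but are not said to mark a shared animal or day. The groups were therefore compared unpaired, as fixed beforehand, and the pairing was tried only as an alternative. Looked at afterwards, the residual profiles of libraries with the same number did not correlate across genes (r = -0.0133, 0.000555 and -0.0108). The other alternatives were RLE and upper-quartile factors, no filter, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a minimum fold of 2, a threshold of 0.1, limma on log2 of FPKM plus 1, and leaving out each library. For the lists they were an estimated correlation, fry, the replicate block, RLE factors and leaving out each library. Alternatives added after the data were seen were an assumed biological coefficient of variation of 0.2 with a likelihood ratio test, genes without exon overlap, protein-coding genes, and upper-quartile factors for the lists.

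The pipeline was tested on simulated data with 200 changed genes. It recovered 100% of genes at a log2 change of -2, 81.6% at -1, 82.5% at 1, and 45 to 47.5% at changes of 0.5 in either direction, and it called 0.0229% of unchanged genes. Of 30 simulated unchanged sets camera called 0, and it called the 1 changed set. Simulated genes varied independently, so the set results do not test how camera behaves when genes of a list correlate. The share of changed genes was also far below that called in the data, so the recovery rates may not carry over. Reads of the eGFP sequence are not part of the table, so reporter transcript was not measured by itself. How far the Trim47 counts include transcripts of the reporter allele is not known.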

Results

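RNA was sequenced from long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that sustain blood formation over the long term. The cells came from Trim47+/eGFP mice, which per the genotype name carry an enhanced green fluorescent protein (eGFP) reporter on one allele of Trim47, a gene of the tripartite motif family of ubiquitin ligases. Cells were separated into a population with low (eGFPlo) and one with high (eGFPhi) reporter fluorescence, with 3 libraries of each. The counts per library summed to 11706873, 14333582 and 18151852 for eGFPlo replicates 1 to 3 and to 11221070, 26058391 and 19460211 for eGFPhi replicates 1 to 3. The design contains a single comparison, eGFPhi against eGFPlo, which asks which transcripts differ between LT-HSCs with high and low Trim47 reporter activity. Levels are CPM, read counts scaled to a common library size with TMM factors, given as mean ± SD over n = 3 libraries per group. Fold changes are eGFPhi over eGFPlo from edgeR quasi-likelihood fits, with their standard error (SE) on the log2 scale and p-values adjusted by the Benjamini-Hochberg method. Gene positions are on mouse build GRCm38.

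Trim47 (ENSMUSG00000020773, chromosome 11, positions 116105752 to 116127210, minus strand) rose from 8.12 ± 0.818 CPM in eGFPlo to 23.7 ± 2.29 CPM in eGFPhi (n = 3 each). This was a 2.91-fold increase (log2 fold change 1.54, SE 0.11, adjusted p = 1.69e-05), and all 3 eGFPhi libraries lay above all 3 eGFPlo libraries. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest value that 3 libraries against 3 allow. Trim65, looked at after its values were seen because it shares 225 bp of exon sequence with Trim47 on the same strand, did not differ past the threshold, at 20.6 ± 1.87 against 19.3 ± 0.553 CPM (log2 fold change -0.09, SE 0.08, adjusted p = 0.373). Cells were sorted on a reporter of Trim47, so its rise checks the sort labels and is not independent of the sort. In the same fit 1399 genes rose more than Trim47.

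The transcriptomes of both populations differed broadly. Of 18081 genes tested, 5840 were higher and 5731 lower in eGFPhi at an adjusted p under 0.05 (edgeR), together 11571 genes or 64.0%. Of these, 2340 rose and 1730 fell at least 2-fold. Rises and falls are relative to the bulk of genes, which TMM factors place near no change. The 3 values of one group lay entirely above those of the other for 12620 genes (69.8%), where chance gives 10%. The first principal component of log2 CPM separated both groups and held 86.5% of the variance, and correlations across genes were 0.986 to 0.990 within a group and 0.882 to 0.892 between groups. The labels do not say that libraries of a group came from separate animals or separate sorts, so the p-values measure only the spread between these samples. That spread was small, with a common biological coefficient of variation of 0.0941; with an assumed coefficient of 0.2, chosen after seeing the data, 6619 genes passed (3637 higher, 2982 lower) in a likelihood ratio test. Granulocyte-monocyte progenitor and B cell genes were far lower in eGFPhi, so for falling and rising lists alike it is not resolved whether a difference lies within LT-HSCs or in the share of other cells in the sorts.

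**Figure D1:**
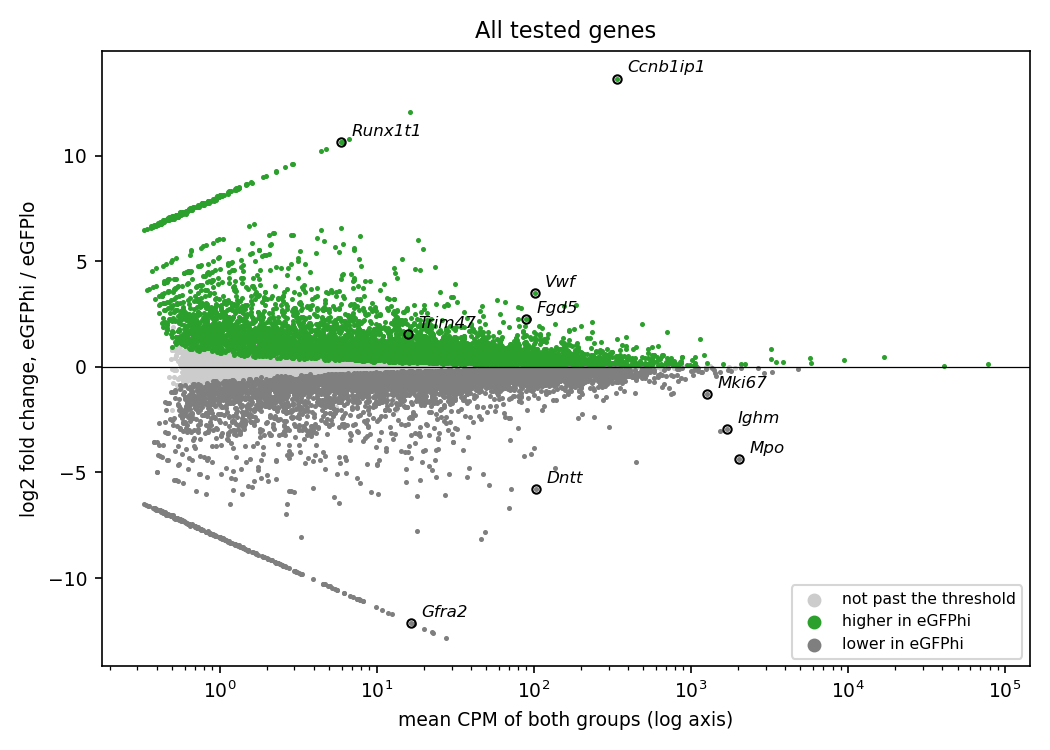
Log2 fold change (eGFPhi over eGFPlo, vertical axis) against mean CPM (horizontal log axis) for the 18081 tested genes, with genes past the adjusted p threshold coloured by direction. The straight outer arms are genes with no count in 1 group, whose fitted fold depends on the prior count; 5840 genes were higher and 5731 lower.

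Genes that characterise LT-HSCs were higher in eGFPhi. Of 28 measured HSC identity genes, 27 rose and 0 fell (28 and 0 adjusted over the list alone), with a median log2 fold change of 1.49. Fgd5 (ENSMUSG00000034037, chromosome 6, 91978878 to 92076004), a guanine nucleotide exchange factor whose expression marks HSCs, rose 4.86-fold from 30.4 ± 1.48 to 148 ± 1.05 CPM (log2 fold change 2.28, SE 0.04, adjusted p = 3.99e-08). The transcription regulator gene Mllt3 rose 3.41-fold from 75.9 ± 3.57 to 258 ± 3.79 CPM. Angpt1, which encodes the Tie2 ligand angiopoietin-1, rose 1.97-fold from 416 ± 6.49 to 818 ± 7.71 CPM. As a set the HSC identity genes were past the threshold by camera (adjusted p = 3.83e-14, and 0.0249 with an estimated correlation).

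Of 22 genes of quiescent HSCs, 15 rose and 4 fell (17 and 4 adjusted over the list alone), with a median log2 fold change of 1.36. Aldh1a1, a retinaldehyde dehydrogenase, rose 5.78-fold from 18.1 ± 0.726 to 104 ± 4.72 CPM. The sulfotransferase gene Sult1a1 rose 34.9-fold from 0.809 ± 0.222 to 28.1 ± 1.27 CPM. Clca3a1, a gene of the calcium-activated chloride channel regulator family, rose 7.51-fold and the transcription factor gene Maff 2.15-fold. By camera the quiescence genes had an adjusted p of 1.50e-04, and adjusted p = 0.0945 with an estimated correlation.

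Of 23 measured megakaryocyte and platelet genes, 18 rose and 2 fell, with a median log2 fold change of 0.84. Vwf (ENSMUSG00000001930, chromosome 6, 125546774 to 125686679), which encodes von Willebrand factor and marks platelet-biased HSCs, rose 11.4-fold from 16.4 ± 0.897 to 187 ± 4.72 CPM (log2 fold change 3.51, SE 0.05, adjusted p = 7.07e-09). Mmrn1, encoding the platelet protein multimerin 1, rose 7.72-fold from 42.6 ± 5.39 to 329 ± 4.63 CPM, and the cation channel gene Trpc6 rose 4.84-fold. Plek, encoding the platelet kinase substrate pleckstrin, went the other way and was 2.28-fold lower. Camera gave these platelet genes an adjusted p of 1.50e-04, and adjusted p = 0.0923 with an estimated correlation.

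**Figure D2:**
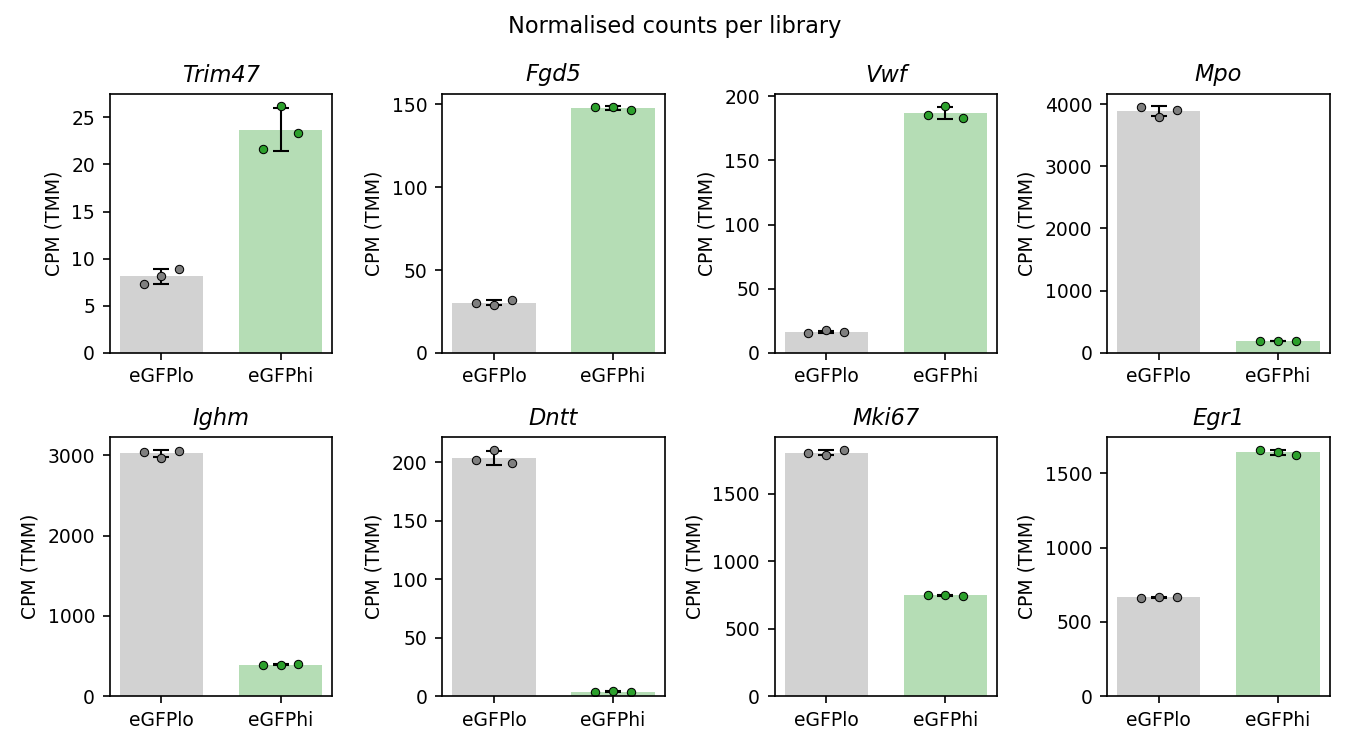
CPM (vertical axis, starting at 0) of Trim47, Fgd5, Vwf, Mpo, Ighm, Dntt, Mki67 and Egr1 in eGFPlo and eGFPhi LT-HSCs; bars are means, error bars SD and points the 3 libraries of each group. In each panel the 3 eGFPhi libraries lie entirely on one side of the 3 eGFPlo libraries, as for Vwf at 16.4 against 187 CPM.

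Genes of granulocyte-monocyte progenitors fell together. All 20 measured members of that list were lower in eGFPhi, with a median log2 fold change of -2.32 and a summed level of 7120 CPM in eGFPlo against 1256 CPM in eGFPhi. Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), which encodes myeloperoxidase, was 20.5-fold lower, at 3885 ± 79.3 against 189 ± 3.44 CPM (log2 fold change -4.36, SE 0.02, adjusted p = 8.98e-11). The genes of the granule proteases neutrophil elastase (Elane, 856 ± 14.1 against 37.8 ± 2.89 CPM), cathepsin G (Ctsg, 265 ± 9.32 against 9.68 ± 0.721 CPM) and proteinase 3 (Prtn3, 183 ± 8.42 against 44.0 ± 0.385 CPM) were 22.7-fold, 27.4-fold and 4.15-fold lower. Tested together by camera, the progenitor genes had an adjusted p of 1.92e-11, and 0.0133 with an estimated correlation. Genes of mature neutrophils showed no common direction: of 16 measured, 5 rose and 3 fell, and the median log2 fold change was 0.11 while the mean was -0.13 (camera adjusted p = 0.691). Among them Fcnb, encoding ficolin B, was 4.76-fold lower, and Retnlg, encoding a resistin-like protein, was 3.36-fold higher at only 1.31 ± 0.128 against 4.39 ± 0.199 CPM.

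Of 12 measured monocyte and macrophage genes, 9 fell and 2 rose, with a median log2 fold change of -1.44. The surface antigen gene Ly6c2 was 14.6-fold lower, at 46.0 ± 5.06 against 3.14 ± 0.364 CPM, and the genes of the adhesion molecule Vcam1, the chemokine receptor Ccr2 and the cytokine receptor Csf1r were 3.36-fold, 3.15-fold and 2.33-fold lower. The set had a camera adjusted p of 0.0166, and adjusted p = 0.191 with an estimated correlation.

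B lineage transcripts were far lower in eGFPhi. Of 18 measured B cell genes, 17 fell and 0 rose, with a median log2 fold change of -5.15 and summed levels of 6567 and 821 CPM. The immunoglobulin mu heavy chain gene Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730) was 7.69-fold lower, at 3026 ± 47.3 against 394 ± 5.57 CPM (log2 fold change -2.94, SE 0.02, adjusted p = 1.44e-10), and the kappa chain gene Igkc was 8.11-fold lower. The B cell transcription factor gene Pax5 was 47.8-fold lower, at 103 ± 1.87 against 2.10 ± 0.378 CPM. The B cell genes had a camera adjusted p of 1.89e-10, and 0.0171 with an estimated correlation. Whether these transcripts came from the LT-HSCs or from other cells of the sort is not resolved by these libraries.

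Of 20 lymphoid priming genes, 14 fell and 4 rose, with a median log2 fold change of -1.55. Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525), encoding the terminal transferase of early lymphoid cells, was 54.8-fold lower, at 204 ± 6.07 against 3.65 ± 0.435 CPM (log2 fold change -5.77, SE 0.07, adjusted p = 4.17e-09). The recombinase gene Rag1 was 68.7-fold lower, at 35.8 ± 2.04 against 0.533 ± 0.0826 CPM, and the B cell linker gene Blnk 282-fold lower, at 92.3 ± 1.998 against 0.391 ± 0.288 CPM. Lymphoid priming genes had a camera adjusted p of 4.95e-04, and adjusted p = 0.0520 with an estimated correlation; without genes that overlap another gene's exons its median log2 fold change was -0.41 and its adjusted p 0.166.

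Of 10 measured T and NK cell genes, 8 fell and 1 rose, with a median log2 fold change of -2.18, and of -3.12 without eGFPlo replicate 2 and -3.07 without eGFPhi replicate 1. The T cell receptor constant genes Trbc1 and Trbc2 stood at 5.84 ± 1.09 and 2.41 ± 0.234 CPM in eGFPlo. In eGFPhi, Trbc2 had no count, which makes it at least 45.5-fold lower (the floor here and below is 3 counts over the group), and Trbc1 had 5 counts, all in replicate 3, so that its 61.5-fold decrease rests on that library and is only a bound without it. The granzyme B gene Gzmb was 10.6-fold and the interleukin receptor gene Il2rb 3.07-fold lower. The set had a camera adjusted p of 0.0166, and adjusted p = 0.123 with an estimated correlation.

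Of 21 measured erythroid genes, 15 fell and 2 rose, with a median log2 fold change of -0.78. The blood group gene Rhd was 9.14-fold lower, at 4.48 ± 0.487 against 0.532 ± 0.233 CPM, the spectrin gene Sptb 3.56-fold lower and the transferrin receptor gene Tfrc 1.77-fold lower. Car2, a carbonic anhydrase gene, rose 1.65-fold from 236 ± 4.99 to 390 ± 15.4 CPM. Erythroid genes had a camera adjusted p of 0.00786, and adjusted p = 0.0923 with an estimated correlation. Of 13 measured stroma and endothelium genes 7 rose and 4 fell, with a median log2 fold change of 0.58 (camera adjusted p = 0.351), which was 1.38 without eGFPlo replicate 3; Kdr, the gene of a receptor for vascular endothelial growth factor, was 18.5-fold higher at 0.303 ± 0.115 against 5.97 ± 0.137 CPM, and the intermediate filament gene Vim was 1.75-fold lower.

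**Figure D3:**
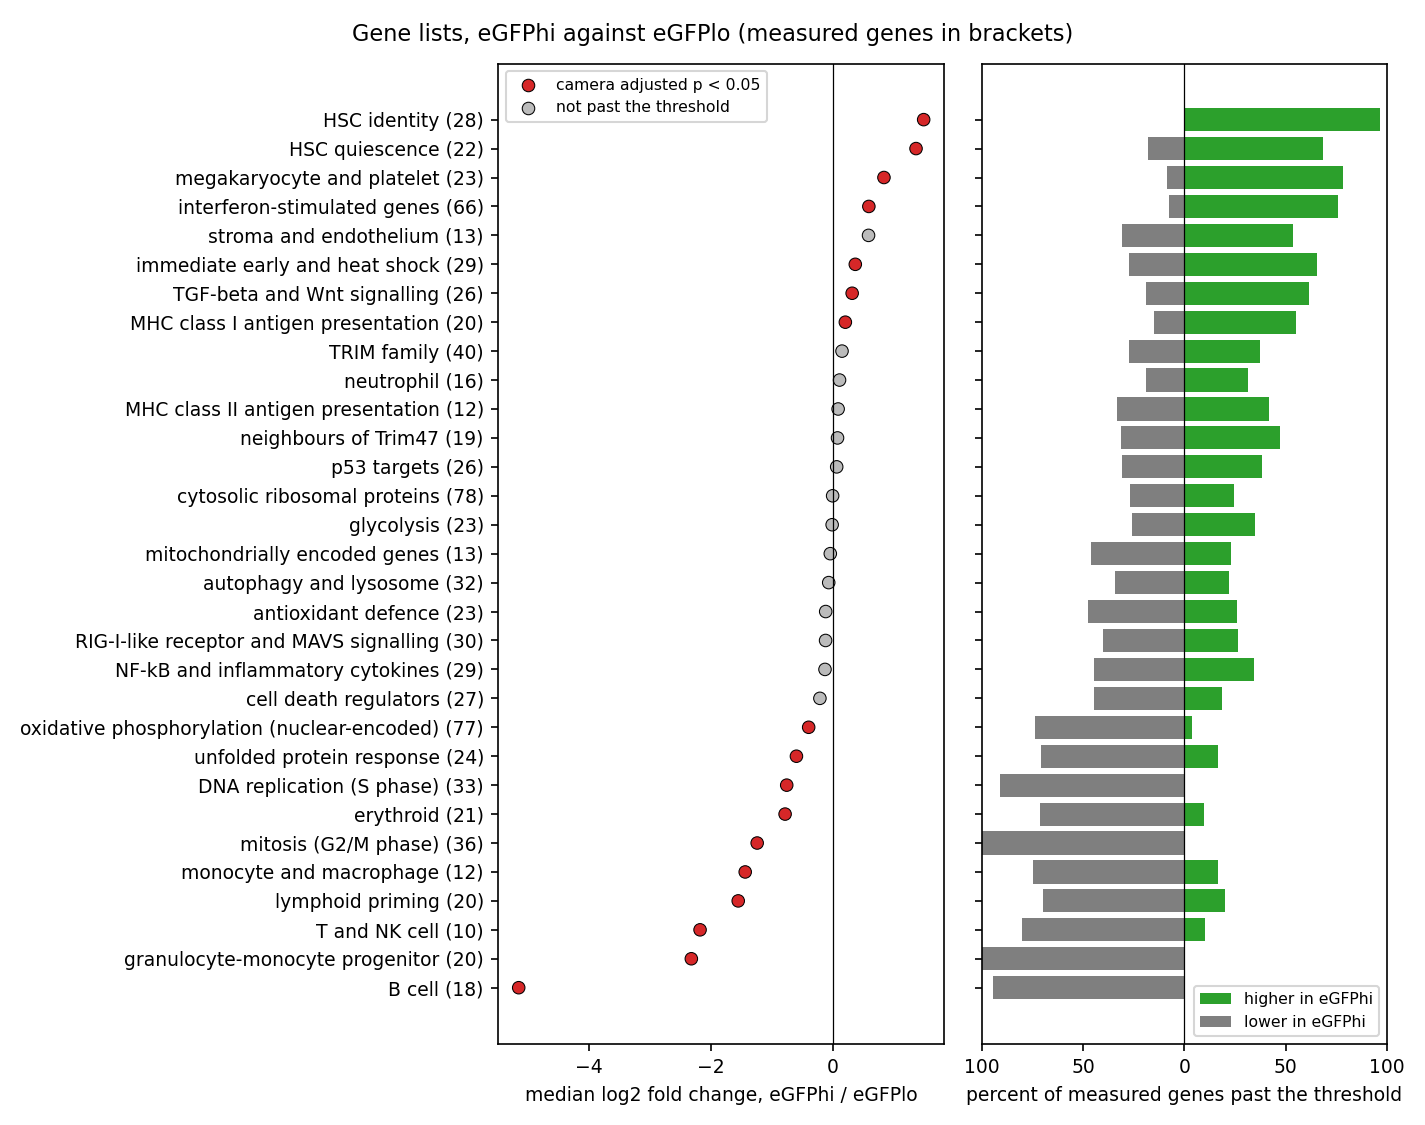
Left, median log2 fold change (eGFPhi over eGFPlo) of the 31 fixed gene lists, with lists past the camera threshold in red; right, percent of measured members higher and lower in eGFPhi. B cell genes have the lowest median, -5.15, and HSC identity genes the highest, 1.49.

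Cell cycle transcripts were lower in eGFPhi. All 36 measured genes of mitosis fell, with a median log2 fold change of -1.24, and of 33 DNA replication genes 30 fell and 0 rose, with a median of -0.76. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), which encodes the proliferation antigen Ki-67, was 2.41-fold lower, at 1803 ± 20.5 against 748 ± 4.48 CPM (log2 fold change -1.27, SE 0.01, adjusted p = 3.62e-09). The genes of the hyaluronan receptor Hmmr (68.4 ± 2.73 against 18.5 ± 0.630 CPM), the centromere kinesin Cenpe (207 ± 3.71 against 69.8 ± 3.74 CPM) and the topoisomerase Top2a (622 ± 9.11 against 263 ± 4.94 CPM) were 3.70-fold, 2.97-fold and 2.37-fold lower. Rrm2, encoding a ribonucleotide reductase subunit, was 4.31-fold lower, and the replicative helicase genes Mcm2, Mcm5 and Mcm6 were 1.98-fold, 1.85-fold and 1.68-fold lower. Camera adjusted p was 1.83e-15 for mitosis and 1.14e-11 for replication, and 0.0133 for each with an estimated correlation. Progenitor and B cell genes fell in the same libraries, from 7120 to 1256 and from 6567 to 821 summed CPM, so whether the cell cycle transcripts came from LT-HSCs or from other cells of the eGFPlo sort is not resolved.

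Interferon-stimulated genes were higher in eGFPhi: of 66 measured, 50 rose and 5 fell, with a median log2 fold change of 0.59, against a fall of progenitor, B cell and cell cycle genes in the same libraries that leaves the cells of origin unresolved. The immunity-related GTPase gene Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634) rose 3.66-fold from 15.3 ± 1.30 to 56.2 ± 3.31 CPM (log2 fold change 1.87, SE 0.08, adjusted p = 1.15e-06). Ifi44 rose 3.29-fold from 13.3 ± 0.822 to 43.8 ± 1.25 CPM, the ISG15-activating enzyme gene Uba7 2.41-fold from 67.4 ± 3.52 to 163 ± 2.39 CPM, and the ADP-ribosyltransferase gene Parp14 1.51-fold. Isg15 and Mx1, chosen after their values were seen, did not pass the threshold, with edgeR adjusted p of 0.162 and 0.354 at levels under 7 CPM in each library. Interferon-stimulated genes together had a camera adjusted p of 1.99e-07, and 0.0249 with an estimated correlation. Genes of RIG-I-like receptor and MAVS signalling, the antiviral RNA-sensing pathway, showed no common direction: of 30 measured, 8 rose and 12 fell (8 and 13 adjusted over the list alone), with a median log2 fold change of -0.12 (camera adjusted p = 0.691). The ubiquitin ligase gene Rnf125 was 1.46-fold higher and the mitochondrial import receptor gene Tomm70a 1.27-fold lower, and neither passed the threshold with an assumed coefficient of variation of 0.2.

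Of 20 MHC class I presentation genes, 11 rose and 3 fell, with a median log2 fold change of 0.20. With an assumed coefficient of variation of 0.2, 2 were higher and 0 lower. The class I genes H2-Q6 (228 ± 1.38 against 336 ± 4.50 CPM), H2-Q7 and H2-Q4, whose similar sequences make read assignment among them uncertain, rose 1.48-fold, 1.48-fold and 1.44-fold, and the class I transactivator gene Nlrc5 rose 1.45-fold. The set had a camera adjusted p of 0.0166, and adjusted p = 0.134 with an estimated correlation. Without genes that overlap another gene's exons its adjusted p was 0.0524 at a median of 0.25, and H2-Q4 and Nlrc5 did not pass with an assumed coefficient of variation of 0.2 (adjusted p = 0.0687 and 0.0625). Of 12 MHC class II presentation genes 5 rose and 4 fell, with a median of 0.09 and a camera adjusted p of 0.691; H2-Aa rose 1.79-fold from 18.9 ± 1.06 to 33.7 ± 0.718 CPM and H2-Eb1 2.10-fold. NF-kB and inflammatory cytokine genes went both ways, with 10 higher and 13 lower of 29 (11 and 13 adjusted over the list alone), a median of -0.13 and a camera adjusted p of 0.493. The NF-kB inhibitor genes Nfkbia (217 ± 2.02 against 127 ± 1.99 CPM) and Tnfaip3 (247 ± 7.25 against 138 ± 1.29 CPM) were 1.70-fold and 1.79-fold lower.

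Oxidative phosphorylation genes of the nucleus were slightly lower in eGFPhi as a set. Of 77 measured, 57 fell and 3 rose (58 and 3 adjusted over the list alone), with a median log2 fold change of -0.40. As for the cell cycle genes, the cells of origin are not resolved, since progenitor and B cell genes fell in the same libraries. Atp5b (ENSMUSG00000025393, chromosome 10, 128083273 to 128090391), encoding a subunit of ATP synthase, was 1.51-fold lower, at 412 ± 14.1 against 273 ± 1.98 CPM (log2 fold change -0.59, SE 0.03, adjusted p = 2.21e-06). Atp5a1 was 1.40-fold, the complex II gene Sdhc 1.77-fold and the complex III gene Uqcrq 1.78-fold lower. For this list the camera adjusted p was 2.83e-08, and 0.0133 with an estimated correlation. Of the 13 mitochondrially encoded genes 3 rose and 6 fell, with a median of -0.04 and a mean of 0.01 (camera adjusted p = 0.664); mt-Nd6, which overlaps mt-Nd5 on the other strand, rose 1.20-fold and mt-Nd1 was 1.17-fold lower.

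Unfolded protein response genes were mostly lower: of 24, 17 fell and 4 rose, with a median log2 fold change of -0.60, in libraries where progenitor, B cell and plasma cell genes fell too, so that the cells of origin are not resolved. Hsp90b1 (ENSMUSG00000020048, chromosome 10, 86690209 to 86705509), which encodes the endoplasmic reticulum chaperone GRP94, was 2.02-fold lower, at 970 ± 17.0 against 479 ± 11.1 CPM (log2 fold change -1.02, SE 0.02, adjusted p = 9.12e-08). Sdf2l1, at 44.7 ± 1.25 against 15.2 ± 0.490 CPM, was 2.92-fold lower, and the disulfide isomerase genes Pdia4 and Pdia3 were 2.15-fold and 1.39-fold lower. For the unfolded protein response the camera adjusted p was 5.35e-04, and adjusted p = 0.0520 with an estimated correlation.

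Immediate early and heat shock genes were higher on balance, with 19 of 29 higher and 8 lower and a median log2 fold change of 0.37. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), a transcription factor gene induced by growth signals, rose 2.47-fold from 665 ± 5.17 to 1642 ± 17.7 CPM (log2 fold change 1.30, SE 0.02, adjusted p = 3.62e-09). The nuclear receptor gene Nr4a2 rose 3.81-fold from 44.8 ± 1.27 to 171 ± 5.78 CPM and Fos 1.39-fold, while the chaperone gene Hsp90aa1 was 1.61-fold lower. With an assumed coefficient of variation of 0.2, 8 genes of the list were higher and 4 lower, and Fos did not pass the threshold. The set had a camera adjusted p of 0.0127, and adjusted p = 0.191 with an estimated correlation.

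TGF-beta and Wnt signalling genes divided: 16 of 26 rose and 5 fell, with a median log2 fold change of 0.32. The TGF-beta pathway genes Tgfbr3 (40.6 ± 0.784 against 131 ± 3.20 CPM), Eng (66.5 ± 2.44 against 156 ± 6.32 CPM) and Ltbp3 (73.6 ± 2.09 against 166 ± 4.44 CPM) rose 3.23-fold, 2.35-fold and 2.26-fold. Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356), a transcription factor gene of the Wnt pathway that lymphoid progenitors also express, was 33.5-fold lower, at 92.9 ± 1.16 against 2.82 ± 0.390 CPM (log2 fold change -5.06, SE 0.09, adjusted p = 2.37e-08). The set passed narrowly by camera (adjusted p = 0.0479), with adjusted p = 0.140 with an estimated correlation. Leaving out a single library also ended the call, at adjusted p = 0.0650 without eGFPlo replicate 2, 0.0550 without eGFPhi replicate 1 and 0.0539 without eGFPhi replicate 2, while the median stayed at 0.30, 0.36 and 0.27.

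The remaining lists showed no common direction by camera. Of 40 TRIM family genes 15 rose and 11 fell (median log2 fold change 0.15, camera adjusted p = 0.281), with Trim27 1.54-fold lower, at 87.5 ± 1.104 against 57.0 ± 0.741 CPM, and Trim44 1.30-fold higher. Among 19 neighbours of Trim47 on chromosome 11, 9 rose and 6 fell (median 0.08, adjusted p = 0.422). Of these Smim6 rose 5.19-fold from 1.20 ± 0.263 to 6.20 ± 0.744 CPM. Of 26 p53 targets 10 rose and 8 fell (median 0.06, adjusted p = 0.691), with the kinase gene Plk2 1.88-fold higher and the DNA repair gene Xpc 1.37-fold lower. Of 27 cell death regulators 5 rose and 12 fell (median -0.21, adjusted p = 0.232), with the survival gene Mcl1 1.33-fold higher and the pro-apoptotic gene Bcl2l11 2.62-fold lower, at 76.0 ± 3.76 against 29.1 ± 3.65 CPM. Trim44, Xpc and Mcl1 did not pass the threshold with an assumed coefficient of variation of 0.2.

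For antioxidant defence 6 of 23 genes rose and 11 fell (median log2 fold change -0.12, camera adjusted p = 0.281), with the glutathione reductase gene Gsr 2.79-fold lower, at 158 ± 4.50 against 56.6 ± 3.95 CPM, and the peroxiredoxin gene Prdx2 1.38-fold lower. For autophagy and lysosome 7 of 32 rose and 11 fell (median -0.07, adjusted p = 0.686), with the cathepsin gene Ctsz 1.73-fold and the neuraminidase gene Neu1 1.85-fold lower. Glycolysis had 8 of 23 entries higher and 6 lower, with a median of -0.01, a mean of 0.11 and a camera direction upward (adjusted p = 0.828). The list holds 22 gene symbols, and entries that share a symbol were each counted. Slc2a3, encoding a glucose transporter, rose 1.52-fold and Pgam1, encoding phosphoglycerate mutase, was 1.94-fold lower. Of 78 cytosolic ribosomal protein genes 19 rose and 21 fell, with a median of -0.00443, a mean of -0.02 and a camera direction upward (adjusted p = 0.855), and Rps7 and Rps14 rose 1.42-fold and 1.30-fold. With an assumed coefficient of variation of 0.2, 2 of these ribosomal genes were higher and 4 lower. Rps7, Rps14 and Prdx2 did not pass the threshold with that coefficient.

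In all, 17 of the 31 lists passed by camera, 7 upward and 10 downward, and 7 of the 17 also passed with an estimated correlation. For the 10 that did not, adjusted p ranged from 9.79e-07 to 0.216 over the 12 alternatives tried for the lists. The counts of higher and lower members in 26 of the 31 lists were the same adjusted over the list alone as over all genes tested.

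Among the genes with the largest increases, 9 had no count in eGFPlo. Smtnl1 (ENSMUSG00000027077, chromosome 2, 84811176 to 84822652), encoding a smoothelin-like protein, stood at 13.4 ± 1.20 CPM in eGFPhi, at least 197-fold higher. The transcription corepressor gene Runx1t1 (11.9 ± 1.94 CPM) was at least 175-fold, the matrix metalloproteinase gene Mmp16 at least 176-fold and the receptor regulator gene Shisa9 at least 176-fold higher. Sytl5, the calcium release channel gene Ryr2, Adgrg2, Dixdc1 and Ppp2r2b were at least 141-fold, 130-fold, 86.7-fold, 85.1-fold and 76.9-fold higher. Ccnb1ip1 (ENSMUSG00000071470, chromosome 14, 50789248 to 50807732) had 2 counts in eGFPlo and 681 ± 7.56 CPM in eGFPhi, but shares 233 bp of exon sequence on the same strand with the abundant RNase P RNA gene Rpph1, looked at after its values were seen (5473 ± 269.7 CPM in eGFPlo and 6214 ± 96.3 CPM in eGFPhi).

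All 10 genes with the largest decreases had no count in eGFPhi. Of these 8 were immunoglobulin variable genes, whose similar sequences make the assignment of reads among them uncertain. Igkv1-135 (ENSMUSG00000096336, chromosome 6, 67609713 to 67610508), at 55.2 ± 1.89 CPM in eGFPlo, was at least 1043-fold lower. Ighv9-3, Ighv1-15, Ighv1-55, Ighv5-9-1, Igkv6-17, Igkv12-41 and Ighv1-76 were at least 854-fold, 762-fold, 653-fold, 471-fold, 412-fold, 375-fold and 308-fold lower. Igll1 (ENSMUSG00000075370, chromosome 16, 16860671 to 16863985), encoding the surrogate light chain of pre-B cells, stood at 45.7 ± 2.18 CPM and was at least 863-fold lower. Gfra2 (ENSMUSG00000022103, chromosome 14, 70890120 to 70979838), encoding a receptor for the neurotrophic factor neurturin, stood at 33.2 ± 6.52 CPM and was at least 626-fold lower. Of the tested genes, 242 had no count in eGFPhi, 79 of them immunoglobulin variable genes, and 178 had none in eGFPlo. Variable genes as a family were not absent from eGFPhi. They summed to 2544 to 2636 CPM in the eGFPlo libraries and 369 to 379 CPM in the eGFPhi libraries (without TMM factors). The bounds above therefore hold for single genes picked as the largest decreases.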

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

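The tests in this part were chosen after the results were seen, apart from the regroupings of the libraries. An RNA outside the tested genes stood out: the 5S ribosomal RNA copy n-R5s193 had 20463 counts (1428 CPM) in eGFPlo replicate 2 and 0 in each of the other 5 libraries. It was singled out because the signal lies in a gene that the low-count filter removed, present in a single library. The 63 genes of 5S RNA summed to 1787 CPM in that library and to 390 to 467 CPM in the others. No biological explanation was tested, and the value enters no comparison.

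The number of genes past the threshold followed the sorted groups. Of the 10 ways to divide the 6 libraries into 3 and 3, 1 gave as many genes as the real groups: the real division called 11571 genes and the highest other called 1. For the gene lists, 1 of 10 divisions gave as many lists, with 17 in the real division and 10 to 13 in the others. Each other division mixes the sorted groups and keeps part of their difference. These divisions therefore do not show how many genes or lists would pass without a difference. With only 10 divisions no share under 0.05 can be reached.

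B lineage transcripts were far lower in eGFPhi, which could reflect B lineage cells in the eGFPlo libraries or stem cells that express these genes. Mature B cells as the main source are argued against, since their abundant Cd74 and MHC class II transcripts summed to 113 ± 6.57 CPM in eGFPlo and 148 ± 4.58 CPM in eGFPhi (a difference of -35.2 CPM), while Ighm and Igkc summed to 5752 ± 49.1 and 730 ± 12.8 CPM. A small share of them stays open, as H2-Ab1 of that sum (1.31-fold), Ms4a1 (33.6-fold) and Cd79b (3.04-fold) were lower in eGFPhi and Ighd had 3.35 ± 0.501 CPM in eGFPlo against no count, and so do antibody-secreting cells, with 9 of 10 plasma cell genes lower. RNA of whole marrow is argued against for most of the pattern, since the neutrophil genes abundant there summed to 299 ± 4.82 CPM in eGFPlo and 305 ± 8.85 CPM in eGFPhi (a difference of -6.38 CPM), although single genes went both ways (S100a8 1.63-fold lower, Lyz2 1.32-fold higher, and the haemoglobin gene Hba-a1 1.52-fold lower in eGFPhi). Early B lineage cells stay open, as all 14 early B progenitor genes, each also in a fixed list, were lower. They cannot be told apart from LT-HSCs that express lineage genes, since both predict the median log2 fold change of -5.15 of the B cell list, no value per cell is available and the gate is not given in the sources used here.

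The libraries of a group were very alike. A library deposited more than once is argued against, since the lowest chi-square per degree of freedom among the 6 pairs within a group was 4.09, above the 1 that resampling of one library gives. A few genes with large differences can raise that value. The median chi-square of single genes was closer to resampling, at 1.63 to 1.87 times its median, though still above it. A pool of cells or RNA shared by the libraries of a group remains a candidate explanation. Immunoglobulin variable genes, whose use would differ between separate small samples of B lineage cells, varied no more than other genes of similar count. The ratio of their median spreads was 0.893 in eGFPhi and 0.722 in eGFPlo. If each library held many B lineage cells, separate samples could give such ratios too, so the ratios alone do not separate a pool from separate samples. All 66 and all 156 such genes with at least 30 counts appeared in all 3 libraries of their group, and their levels correlated across genes at 0.962 or more within a group and 0.572 between groups. A few genes spread widely within a group, with Jchain, itself a B lineage gene, at 333 ± 175 CPM in eGFPlo, Hoxa7 at 31.5 ± 18.2 CPM in eGFPlo and Hlf at 483 ± 106 CPM in eGFPhi, which a shared pool alone leaves unexplained. Low spread between separate animals of one strain was not tested, and if libraries share a pool the p-values describe preparation and sequencing alone.

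Ccnb1ip1 had 2 counts in eGFPlo and 38726 in eGFPhi, a ratio of 15072 (95% counting interval 4172 to 124454). Reads of the overlapping gene Rpph1 counted for Ccnb1ip1 in the eGFPhi libraries are a candidate source. The summed CPM of both genes had a log2 ratio of 0.33 (0.333), inside the range of 0.24 to 0.45 of 4 other small structural RNAs, whereas Rpph1 alone had 0.18. Ccnb1ip1 took 9.78 to 9.94% of the sum in the eGFPhi libraries, a nearly constant share. Reads shared on the same strand are argued against for most other genes present in 1 group alone. These were genes with at least 5 CPM in a group and at most 3 counts in the other, immunoglobulin genes aside. Of them, 3 of 24 overlap another gene on the same strand (12.5%, against 8.30% of all tested genes), which leaves 21 without such overlap. Overlap on the other strand, as of Adgrg2 with Gm15241, was not counted, so reads shared in that way stay open.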

How the results depend on the processing

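Trim47, on whose reporter the cells were sorted, stayed higher in eGFPhi and past the threshold under all 18 alternatives that gave a test for it, with log2 fold changes of 1.104 (log2 of FPKM plus 1) to 1.62 and adjusted p of 5.20e-20 to 2.02e-04. All 117 genes selected by the naming rule passed in the reported analysis, since apart from Trim47 the rule took genes past the threshold. They also passed with each library left out, which says little for genes picked by strength from the same 6 libraries. Single genes among them dropped below the threshold in 54 cases, all under a minimum fold of 2 or the assumed coefficient of variation, and none changed direction in the alternatives that gave it a value. Those lost under the assumed coefficient were Rnf125, Tomm70a, H2-Q4, Nlrc5, Xpc, Mcl1, Atp5a1, mt-Nd6, mt-Nd1, Rps7, Rps14, Fos, Pdia3, Prdx2 and Trim44.

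The count of genes changed by more than 1.5 times under 2 alternatives. A minimum fold of 2 left 4070 (2340 higher, 1730 lower), by its construction. An assumed coefficient of variation of 0.2, added after seeing the data, left 6619 (3637 higher, 2982 lower), with a larger spread and a likelihood ratio test together; which of these lowered the count was not tested. Elsewhere the count lay between 8346 (protein-coding genes only, added after seeing the data) and 13683 (no filter), with 9761 in DESeq2 and 10965 with the replicate block. Leaving out 1 library gave 10618 to 11427 genes. RLE and upper-quartile factors moved the median of all genes by at most 0.0249, and 50.3% and 52.8% of called genes were then higher, against 50.5%. Like TMM, these factors place the bulk of genes near no change. Exchanging them therefore cannot test the near-even split or a difference in RNA content per cell.

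Among lists, 17 passed in the reported analysis, 7 with an estimated correlation and 26 with fry, which does not compare a list with other genes; for the estimated correlation the cause was not tested. With RLE factors 17 passed, with the replicate block 16, with upper-quartile factors 16, without 1 library 16 to 17 and without overlapping genes 14. Without overlapping genes 3 lists were lost: the median of lymphoid priming went from -1.55 to -0.41 (adjusted p = 0.166), that of MHC class I from 0.20 to 0.25 (0.0524) and that of TGF-beta and Wnt from 0.32 to 0.23 (0.216). TGF-beta and Wnt was also lost with the block (0.0532) and upper-quartile factors (0.0538), with medians of 0.32 and 0.34. The cause of these losses was not tested.

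Medians near 0 changed sign, and the cause was not tested. Without overlapping genes, MHC class II went to -0.157, mitochondrially encoded genes to 0.0140, ribosomal proteins to 0.0118 and autophagy to 0.0622. With upper-quartile factors, glycolysis went to 0.0127 and ribosomal proteins to 0.0205. With 1 library left out, glycolysis ranged from -0.0696 to 0.0642, positive without eGFPlo replicate 1 (0.0642) or 3 (0.00396). Ribosomal proteins ranged from -0.0150 to 0.0175, positive without eGFPlo replicate 3 (0.00377), eGFPhi replicate 1 (0.0175) or eGFPhi replicate 3 (0.0156).

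Over the 500 most variable genes the highest correlation between groups was -0.374, against 0.892 over all tested genes, since such genes are picked for their spread. The alternatives for a file of normalized values alone were not run, as the file holds counts. Overlap of lists with called genes was enriched for 6 lists among higher and 10 among lower genes, and for 6 and 9 under the stricter filter. Depth limits genes near the floor, where the fold is a bound.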

Other observations

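The genes and gene groups here were chosen after the values were seen, so their adjusted p-values, over 11 such groups, are descriptive. Imprinted genes were mostly higher in eGFPhi: of 20 measured, 18 rose and 1 fell, with a median log2 fold change of 2.06 (camera adjusted p = 1.40e-06, and 0.0284 with an estimated correlation). Grb10, an adaptor of growth factor receptors, rose 7.12-fold from 19.6 ± 4.36 to 140 ± 0.575 CPM (n = 3 each), and Igf2r rose 2.29-fold. Peg3 had 2 counts in eGFPlo and 232 in eGFPhi, a ratio of 90.3 (95% counting interval 24.7 to 750.0). Gnas was slightly lower (log2 fold change -0.11).

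Of 15 measured Hox genes, 14 rose and 0 fell, with a median log2 fold change of 1.69 (camera adjusted p = 7.08e-06, and adjusted p = 0.0531 with an estimated correlation). Hoxa5 rose 3.74-fold from 9.34 ± 0.698 to 35.03 ± 0.841 CPM, and Hoxb6 6.88-fold.

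Of 61 replication-dependent histone genes, 59 fell and 1 rose, with a median log2 fold change of -1.10 (camera adjusted p = 3.03e-21, and 0.0233 with an estimated correlation). Hist1h2ao was 2.32-fold lower, at 1078 ± 16.3 against 465 ± 13.6 CPM. Most transcripts of these genes lack a poly(A) tail, so a poly-T selected library measures them only in part, and progenitor, B cell and cell cycle genes fell in the same libraries, so the cells of origin are not resolved.

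Of 230 small nucleolar RNAs, 165 rose and 9 fell, with a median log2 fold change of 0.88 (camera adjusted p = 2.08e-13, and 0.0268 with an estimated correlation). Of 23 small Cajal body RNAs 18 rose and 0 fell, with a median of 1.005, and of 96 small nuclear RNAs 55 rose and 9 fell, with a median of 0.56 (adjusted p = 0.104 with an estimated correlation). These RNAs mostly lack a poly(A) tail, so the poly-T selected libraries measure them only in part. The summed share of the abundant small RNAs Rn7s1, Rn7s2, Rn7sk, Rpph1 and Gm24447 in the counts also differed between the groups. It was 2.50 to 2.52% in the eGFPlo libraries and 3.07 to 3.15% in the eGFPhi libraries. That of mitochondrial ribosomal RNA was 11.2 to 11.6% and 12.2 to 12.3%. A difference in how much RNA without a tail passed the selection therefore stays open for these classes. The histone transcripts above, which mostly lack a tail too, went the other way, from 7438 to 3698 summed CPM. Such a difference alone thus leaves the histone genes unexplained. Malat1 took about 1.41% of counts in each eGFPlo library and 1.97 to 1.98% in each eGFPhi library.

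Of 10 plasma cell genes 9 fell and 0 rose, with a median log2 fold change of -2.07. The immunoglobulin alpha gene Igha stood at 533 ± 10.6 against 74.5 ± 1.76 CPM.

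Some genes whose products are used to sort HSCs were looked at singly, with no test of them as a group. Slamf1, encoding CD150, rose 7.54-fold and Procr, encoding the endothelial protein C receptor, 3.35-fold. Kit rose 1.45-fold, and Ly6a, encoding Sca-1, did not pass the threshold (log2 fold change 0.50, edgeR adjusted p = 0.0623). Cd48 was 4.82-fold, Flt3 2.28-fold and Cd34 1.65-fold lower. Cdk6, a kinase gene of cell cycle entry, was 2.46-fold lower. Mavs did not differ past the threshold (log2 fold change -0.05, edgeR adjusted p = 0.507). The transcription factor gene Mecom rose 3.79-fold.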
